A study of Mus musculus with 22 samples.

How the data were processed

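The deposited table was read as supplied, with 16553 rows of which 84 were ERCC spike-ins and 16469 were genes, and 22 signal columns. The signal of each column is a deposited value per gene that the authors scaled to the spike-ins, and no column was left out. The design fixed before the data were examined assumed read counts, whereas the file holds normalized values. The test planned for that case, limma with a trend on log2 of the deposited value plus 1, was therefore used on the deposited scale. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq, trimmed with Trim Galore 0.6.7, aligned to GRCm39 with STAR 2.7.9a, quantified with Salmon 1.5.2 and normalized in R 4.1.1 with DESeq2 1.32.0. The kit primes at the 3' end of transcripts, and no molecular barcodes were used here, so reads that are copies of the same molecule were not removed.

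Whole reads were recovered from the deposited values by finding 1 factor per library that turned every value into a whole number within 0.001, which held for 100% of values. The recovered factors were 0.938 to 0.981 times factors computed from the spike-in reads alone, and 0.56 to 1.53 times factors computed from genes. Libraries held 7152596 to 15101565 reads in all. Replicates of a group differed more than counting alone gives, with a chi-square per degree of freedom of 12.4 to 79.1 over pairs (median 30.4). Controls 28 and 29 gave 17.55 with each other and 40.87 to 79.08 with the other controls, and they were left out in 1 fit because they stood apart in Saa1 and Hprt.

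Genes with a deposited value of at least 10 in at least 3 libraries were kept for limma (11159 genes). All 22 libraries of the 4 groups were fitted together and p values were adjusted by the Benjamini-Hochberg method within each comparison, with calls at 0.05. Beside it, the recovered reads were tested with edgeR quasi-likelihood fits after TMM scaling and filterByExpr (10766 genes), because the spike-in scale spread the libraries of a group widely. The limma test called 23, 51, 30, 0 and 1 genes and the read-count test called 541, 764, 593, 10 and 292 genes in the order 0.2 mg/kg, 2 mg/kg, 2 against 0.2 mg/kg, BLT-1 against 0.2 mg/kg and BLT-1 against controls. Fold changes by limma are printed relative to the median of all genes, and their p values test the unshifted change. Software was R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.

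Hprt and Scarb1 were tested by exact permutation of the group labels on TMM-scaled CPM and on the deposited scale, two-sided, adjusted over the comparisons. Gene lists, 34 in all with 685 members of which 647 were in the table and 548 tested, were tested with limma camera at a correlation of 0.01, with an estimated correlation and with fry, adjusted over the lists. A list count adjusted over the list alone used only the p values of its members.

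Named genes followed a rule. Hprt and Scarb1 were always named. The 10 highest and 10 lowest called genes of a comparison qualified if the higher group mean was at least 5 CPM or 20 deposited units and every library of the first group lay on 1 side of the mean of the second group, leaving out predicted and unnamed genes. Up to 4 called members of each list with the smallest adjusted p and up to 2 members of highest level of lists without a call were added. Where under 5 genes were called, the 5 with the smallest p were named as not called. The text takes examples from these sets.

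Other settings run were pseudocounts 0.5 and 10, no filter, only the groups compared, animal number ranges as a block, a limit of 0.01, size factors from spike-ins, RLE size factors, DESeq2, limma voom with quality weights, and each library left out in turn. These, the groups, tests, lists and naming rule were fixed before the data were examined. The read-count test with TMM and its settings, the TMM rescaling of deposited values and the fit without controls 28 and 29 were chosen after. The pipeline was tested on simulated data, with planted changes of 1.5, 2 and 4-fold in 200 genes per run and with 1 planted list, which was called in all 5 comparisons with 0 of 33 random lists. Overlap was compared with 20 simulated data sets that shared controls and with controls split into 3 and 4 livers. No intervals were computed.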

Results

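The data were 3' end mRNA libraries from 22 perfused livers of C57BL6J mice, each taken 24 h after an injection of lipid nanoparticles that carried a Dicer-substrate RNA, or from controls. The column names of the deposited table name Hprt as the target of the RNA. There were 7 controls, 8 livers at 0.2 mg/kg, 4 livers at 0.2 mg/kg after BLT-1 at 1 mg/kg given 24 h before the particles, and 3 livers at 2 mg/kg. The labels give no treatment for the controls, and no group had BLT-1 alone. Each library held 7152596 to 15101565 reads, and between 14317 and 14649 genes were detected per library as group means. Spike-in reads made up 4.30 ± 1.22% of the reads in controls, 5.04 ± 1.23% at 0.2 mg/kg, 4.44 ± 1.60% with BLT-1 and 5.64 ± 1.41% at 2 mg/kg (mean ± SD; n = 7, 8, 4 and 3). Mitochondrial transcripts made up 15.9 ± 0.865%, 14.6 ± 0.743%, 14.7 ± 0.361% and 15.7 ± 0.303% in the same order.

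Hprt (ENSMUSG00000025630.9), the purine salvage enzyme named as the target, was read first in every library. At 2 mg/kg its 3 libraries held 15.5, 17.6 and 12.9 CPM (reads scaled by TMM), all below the lowest of the 7 controls (25.0; highest 39.04). The mean was 15.3 ± 2.35 against 30.3 ± 4.93 in controls. By the difference of mean log2 values Hprt was at 50.8% of controls (exact permutation test, two-sided p = 0.00833, the smallest value that these group sizes allow; adjusted p = 0.0417). Against the 8 livers at 0.2 mg/kg (27.8 ± 1.49) the level at 2 mg/kg was 54.7% by the same measure (exact two-sided p = 0.00606, also the smallest possible; adjusted p = 0.0417). Hprt was not called at 0.2 mg/kg against controls (exact two-sided p = 0.248), with BLT-1 against 0.2 mg/kg (27.1 ± 1.94, n = 4; exact two-sided p = 0.475) or with BLT-1 against controls (exact two-sided p = 0.252). On the deposited spike-in scale Hprt was 43.1% of controls at 2 mg/kg, with exact two-sided p = 0.0167 and adjusted p = 0.0835.

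Scarb1 (ENSMUSG00000037936.16), the high-density lipoprotein receptor that BLT-1 blocks, was not called in any comparison by the exact test, limma on the deposited scale or edgeR. Limma voom called it at 0.2 mg/kg against controls (log2 -0.23, adjusted p = 0.0371). Its level was 21.1 ± 2.44 CPM in 7 controls, 18.5 ± 1.44 in 8 livers at 0.2 mg/kg, 19.5 ± 0.896 in 4 livers with BLT-1 and 21.4 ± 2.37 in 3 livers at 2 mg/kg. The smallest exact two-sided p values were 0.0242 for 2 mg/kg against 0.2 mg/kg and 0.0322 for 0.2 mg/kg against controls (adjusted p = 0.0805 for each). With BLT-1 against 0.2 mg/kg the read-count fold change was log2 0.08 (adjusted p = 0.959), and the value was 0.09 by limma relative to the median of all genes (adjusted p = 0.994).

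**Figure D1:**
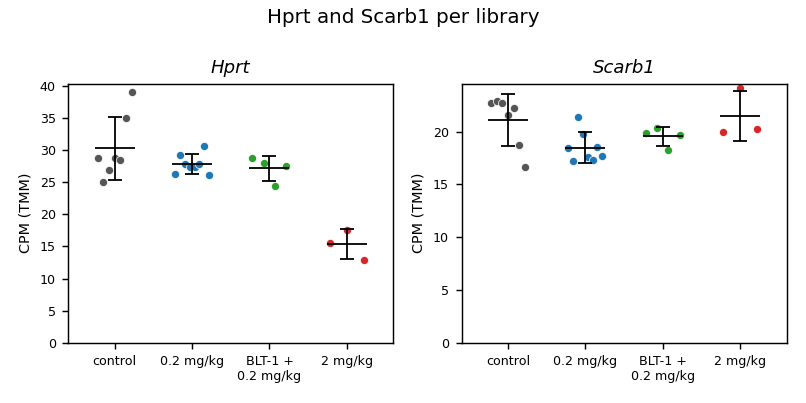
Hprt and Scarb1 in CPM (vertical axis) in each of the 22 livers, by group on the horizontal axis (n = 7, 8, 4 and 3). Points are livers and bars are means ± SD, with Hprt at 30.3 ± 4.93 in controls and 15.3 ± 2.35 at 2 mg/kg.

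The first comparison asked which liver transcripts differed 24 h after 0.2 mg/kg of particles (n = 8) from controls (n = 7). Levels here and below are TMM-scaled CPM as mean ± SD, and log2 fold changes carry a standard error and are given relative to the median of all genes on the deposited scale. That median was log2 -0.11 here, -0.23 for 2 mg/kg against controls, -0.12 for 2 mg/kg against 0.2 mg/kg, 0.16 for BLT-1 against 0.2 mg/kg and 0.05 for BLT-1 against controls. Zbp1, a sensor of Z-form nucleic acids, rose from 11.2 ± 3.20 to 43.1 ± 4.59 (log2 fold change 1.99 ± 0.27, adjusted p = 0.00194). Gbp3, a guanylate-binding protein, rose from 2.08 ± 0.540 to 10.8 ± 3.67 (2.31 ± 0.31, adjusted p = 0.00194). The chemokine gene Cxcl9 rose from 8.23 ± 2.31 to 47.2 ± 31.2 (2.39 ± 0.35, adjusted p = 0.00222). Irf7, which encodes a transcription factor of the interferon response, rose from 8.13 ± 2.27 to 27.7 ± 4.20 (1.81 ± 0.26, adjusted p = 0.00222). Isg15, a ubiquitin-like modifier, rose from 29.8 ± 9.99 to 138 ± 43.2 (2.25 ± 0.37, adjusted p = 0.00551), and the immunoproteasome subunit gene Psmb8 from 13.8 ± 2.42 to 41.2 ± 5.62 (1.57 ± 0.25, adjusted p = 0.00507).

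Of 32 tested genes of the type I interferon list, 9 rose, 0 fell and 23 did not pass, and 26 rose when adjusted over the list alone (median 1.29; camera adjusted p = 2.93e-86; adjusted p = 0.00551 with an estimated correlation). In read counts 26 of 32 rose. Of 26 genes of the interferon gamma list 8 rose and 0 fell (15 of 25 rose in read counts), and 16 rose when adjusted over the list alone (median 1.12; camera adjusted p = 6.87e-55; adjusted p = 0.00969 with an estimated correlation). Ifi44, an interferon-induced GTP-binding protein, and Igtp, an immunity-related GTPase, were among the risen members at 36.8 ± 11.3 and 43.4 ± 13.1 against 7.24 ± 2.38 and 10.5 ± 2.08 in controls. The remaining lists had no gene called by limma. Fatty acid oxidation with PPARalpha targets (28 genes, median -0.34) moved down by camera (adjusted p = 4.19e-12; adjusted p = 0.555 with an estimated correlation). In read counts 9 of its genes fell, among them Ehhadh, a peroxisomal enzyme (-1.33, adjusted p = 0.0251), Acot1, an acyl-CoA thioesterase (-0.93, adjusted p = 0.00417), and Cyp4a10, a fatty acid hydroxylase, at 56.9 ± 6.20 against 96.5 ± 29.2 (-0.76, adjusted p = 0.00137). The unfolded protein and integrated stress response list (24 genes, median -0.35) was lower by camera (adjusted p = 2.54e-08; adjusted p = 0.631 with an estimated correlation). Its 10 members that fell in the read counts included Sdf2l1, an endoplasmic reticulum chaperone partner, at 11.7 ± 0.833 against 21.5 ± 6.56 (-0.88, adjusted p = 0.000566), and Creld2, a secreted stress protein (-1.11, adjusted p = 0.0214).

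The NRF2 and metallothionein list (21 genes, median 0.353) was higher by camera (adjusted p = 2.54e-08; adjusted p = 0.555 with an estimated correlation), with 13 genes risen in the read-count test. These included Ugdh, a UDP-glucose dehydrogenase, at 60.4 ± 5.05 against 31.6 ± 3.58 (0.93, adjusted p = 1.9e-07). Gstm3, a glutathione transferase, was at 73.2 ± 9.71 against 40.3 ± 5.46 (0.86, adjusted p = 6.14e-05). Among 17 Kupffer cell genes (median -0.278; camera adjusted p = 2.8e-05; adjusted p = 0.786 with an estimated correlation) 3 fell and 1 rose in the read counts. Cd163, a haemoglobin scavenger receptor, fell from 1.42 ± 0.377 to 0.638 ± 0.201 (-1.14, adjusted p = 0.00132), Vsig4, a complement receptor, fell by 0.71 (adjusted p = 0.00693), and Slc40a1, the iron exporter, rose by 0.45 (adjusted p = 0.00486). Of 9 monocyte genes (median 0.50; camera adjusted p = 2.53e-06; adjusted p = 0.245 with an estimated correlation) 4 rose in the read counts, with Ly6c2, a marker of inflammatory monocytes, at 7.29 ± 5.01 against 1.47 ± 0.854 (2.30, adjusted p = 0.00552). Pecam1, an endothelial adhesion molecule, rose in read counts from 11.6 ± 5.44 to 29.6 ± 11.1 (1.36, adjusted p = 0.00565). It was the only one called of 17 sinusoidal endothelial genes, and that list was not higher (median -0.122; camera adjusted p = 0.27). Camera calls for 7 T and NK cell genes (median 0.404, adjusted p = 0.00612) and 19 gluconeogenesis genes (median -0.162, adjusted p = 0.0201) were lost with an estimated correlation (adjusted p = 0.198 and 0.928 with an estimated correlation). Of 17 purine genes 0 passed by limma (camera adjusted p = 0.155), and 2 rose in read counts, with Xdh, the xanthine dehydrogenase, at 24.0 ± 1.95 against 13.4 ± 2.00 (0.85, adjusted p = 1.2e-06). In all, camera called 9 of 34 lists, 5 up and 4 down, and only the interferon pair held here with an estimated correlation. In read counts the interferon pair and the NRF2 list held (adjusted p = 0.00163, 0.00163 and 0.00182 with an estimated correlation).

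Limma on the deposited values called 23 of 11159 genes at 0.2 mg/kg, 23 higher and 0 lower, with 438 genes at unadjusted p below 0.05. By chance that limit passes a share of 0.05 of unchanged genes, and 438 is below that share. Among the limma counts given this way for the comparisons, only that of 2 mg/kg against controls is above it. The edgeR test of the recovered reads called 541 of 10766 genes, 298 higher and 243 lower, and included all 23. Leaving out single livers moved the limma count from 18 to 32. In planted changes limma recovered 0%, 19.5% and 89.2% of genes at 1.5, 2 and 4-fold (10590 genes run), and edgeR 39.1%, 79.3% and 93.8% (10503 genes), so small changes went mostly uncalled on the deposited scale. Unchanged genes made up 3.9% of the limma calls and 7.36% of the edgeR calls in these planted data.

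**Figure D2:**
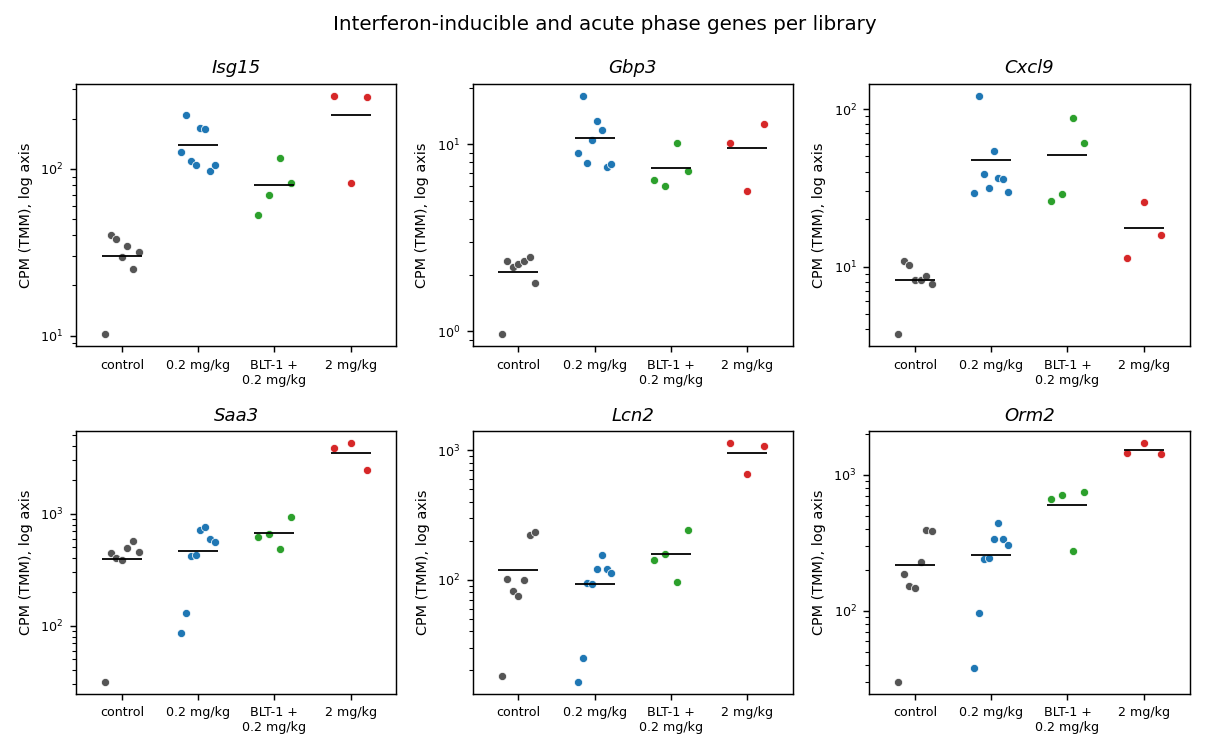
Interferon and acute phase genes in CPM on a log scale (vertical axis) in each of 22 livers, by group on the horizontal axis (n = 7, 8, 4 and 3). Points are livers and bars are means, with Isg15 at 29.8 in controls and 138 at 0.2 mg/kg, and Saa3 at 397 and 461.

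The question of the next comparison was which transcripts differed after 2 mg/kg (n = 3) from controls (n = 7). These 3 livers also held Xist and fewer Y-linked reads, as given below. In every comparison of 2 mg/kg the dose was not separable from that pattern. Saa3, an acute phase apolipoprotein, rose from 397 ± 172 to 3513 ± 926 (log2 fold change 3.45 ± 0.61, adjusted p = 0.0123), and Lcn2, an iron-binding lipocalin, from 119 ± 79.1 to 954 ± 259 (3.31 ± 0.60, adjusted p = 0.0133). Apcs, the serum amyloid P component, rose from 180 ± 124 to 705 ± 120 (2.22 ± 0.42, adjusted p = 0.0205). Ifit1, which binds RNA without a 2'-O-methylated cap, rose from 6.37 ± 1.88 to 49.5 ± 28.6 (2.76 ± 0.42, adjusted p = 0.00369). Il1rn, the interleukin 1 receptor antagonist, rose from 1.28 ± 0.562 to 5.78 ± 2.58 (2.09 ± 0.38, adjusted p = 0.0169). Cyp7b1, an oxysterol hydroxylase with higher levels in male liver, fell from 68.7 ± 13.5 to 27.1 ± 8.63 (-1.38 ± 0.31, adjusted p = 0.0123).

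Several called genes at 2 mg/kg have sex-biased levels in mouse liver. Sult2a1, a steroid sulfotransferase, rose from 0.393 ± 0.302 to 22.8 ± 12.2 (5.73 ± 0.80, adjusted p = 0.00142). Cyp3a41a, a female-biased P450, rose from 2.08 ± 0.817 to 96.9 ± 47.3 (5.51 ± 0.93, adjusted p = 0.00527), and Cyp2a4, a steroid 15-alpha hydroxylase, from 6.10 ± 0.859 to 42.3 ± 12.6 (2.73 ± 0.31, adjusted p = 0.000204). Sult3a1, an amine sulfotransferase, reached 38.7 ± 14.8 against 1.16 ± 0.586 in controls (5.13 ± 0.85, adjusted p = 0.00527). Xist, the RNA that coats the inactive X chromosome, rose from 0.161 ± 0.0959 to 3.99 ± 1.05 (4.12 ± 0.69, adjusted p = 0.00527). Mup7, a major urinary protein, fell from 9803 ± 1889 to 2746 ± 1061 (-1.90 ± 0.31, adjusted p = 0.00142), and Serpina1e, an alpha-1 antitrypsin copy, from 1990 ± 437 to 643 ± 159 (-1.65 ± 0.31, adjusted p = 0.00396). Of 5 tested genes of the sex chromosome list 1 rose, 1 fell and 3 did not pass, and adjusted over the list alone 1 rose and 2 fell (median -0.306; camera adjusted p = 0.589). Ddx3y, a Y-linked RNA helicase, fell from 17.2 ± 0.971 to 7.54 ± 1.20 (-1.20 ± 0.32, adjusted p = 0.0365), a call lost in 7 of 10 fits that left out 1 liver. Eif2s3y, a Y-linked translation factor, was at 3.73 ± 0.360 against 7.30 ± 2.04 and fell in the read-count test (-0.97, adjusted p = 0.00101). Reads of the Mup, Sult2a, Cyp2a, Cyp2b, Cyp3a41, Serpina1, Orm, Saa, Ifit3, Gbp and H2 families are hard to assign to single members because the copies are nearly identical.

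**Figure D3:**
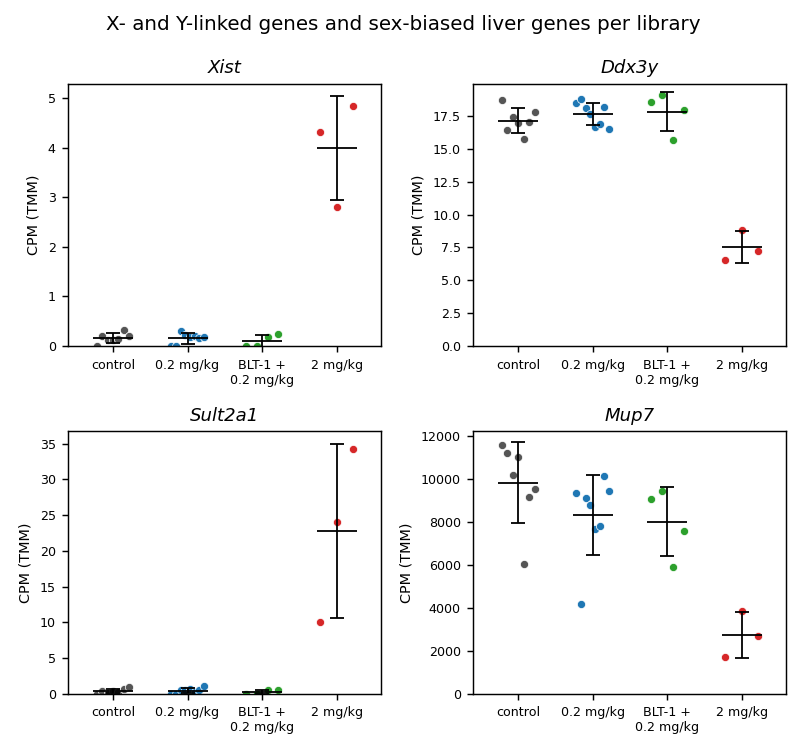
Xist, Ddx3y, Sult2a1 and Mup7 in CPM (vertical axis) in each of 22 livers, by group on the horizontal axis (n = 7, 8, 4 and 3). Points are livers and bars are means ± SD, with Xist at 0.161 ± 0.0959 in controls and 3.99 ± 1.05 at 2 mg/kg and Ddx3y at 17.2 ± 0.971 and 7.54 ± 1.20.

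By list at 2 mg/kg, 8 of 32 type I interferon genes rose and 0 fell, and 27 rose adjusted over the list alone (median 1.68; camera adjusted p = 5.54e-73; adjusted p = 0.013 with an estimated correlation). In read counts 30 of 32 rose. Of 31 acute phase genes 5 rose and 0 fell (15 rose in read counts), and 15 rose adjusted over the list alone (median 1.05; camera adjusted p = 1.22e-36; adjusted p = 0.0288 with an estimated correlation). Orm2, an acute phase lipocalin, was at 1528 ± 149 against 218 ± 132 (3.13 ± 0.60, adjusted p = 0.0183). Of 4 neutrophil genes tested out of 15 listed 1 rose, and 3 rose adjusted over the list alone (median 1.69; camera adjusted p = 7.25e-11; adjusted p = 0.0151 with an estimated correlation). The called gene was Lcn2, which is also in the acute phase list, so the 2 lists are not separate evidence. None of 7 T and NK cell genes passed alone, although the list was called (median 0.794; camera adjusted p = 2.92e-05; adjusted p = 0.0206 with an estimated correlation). Of 20 cytokine, chemokine and NF-kB target genes 2 rose (7 of 18 in read counts), and 4 rose adjusted over the list alone (median 0.708; camera adjusted p = 7.7e-12; adjusted p = 0.112 with an estimated correlation). Ccl7, a monocyte chemokine, rose from 0.785 ± 0.682 to 3.27 ± 0.699 (2.28 ± 0.43, adjusted p = 0.0216). The interferon gamma list had 1 gene risen of 26 (13 of 25 in read counts), and 3 adjusted over the list alone (median 0.991; camera adjusted p = 2.91e-17; adjusted p = 0.191 with an estimated correlation). In read counts with an estimated correlation the type I interferon (adjusted p = 0.00547) and cytokine lists (adjusted p = 0.024) were called. The acute phase (adjusted p = 0.104), neutrophil (adjusted p = 0.149) and T and NK cell lists (adjusted p = 0.104) were not. By fry no list was called at 2 mg/kg against controls, with acute phase genes at adjusted p = 0.228 and type I interferon genes at adjusted p = 0.0564.

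Among metabolic lists, 0 of 28 fatty acid oxidation genes passed, and 8 fell adjusted over the list alone (median -0.52; camera adjusted p = 3.85e-11; adjusted p = 0.453 with an estimated correlation). In read counts 15 of these genes fell, such as Fabp1, the liver fatty acid binding protein (-0.87). Of 18 bile acid genes 2 fell and 3 fell adjusted over the list alone (median -0.403; camera adjusted p = 1.56e-06; adjusted p = 0.59 with an estimated correlation). Slco1a1, an organic anion transporter, fell from 35.1 ± 9.90 to 13.2 ± 3.95 (-1.40 ± 0.37, adjusted p = 0.0458), a call lost in 8 of 10 fits that left out 1 liver. Cyp8b1, the sterol 12-alpha hydroxylase, fell only in the read counts, from 61.0 ± 10.6 to 29.98 ± 4.40 (-1.02, adjusted p = 0.00028). In the fatty acid synthesis list 0 of 20 genes passed and 5 fell adjusted over the list alone (median -0.387; camera adjusted p = 2.35e-06; adjusted p = 0.59 with an estimated correlation). Scd1, the stearoyl-CoA desaturase, fell in read counts (-0.68, adjusted p = 0.00109). Of 24 xenobiotic genes 4 rose and 0 fell, while 4 rose and 5 fell adjusted over the list alone. The median of that list was -0.143 although the camera direction was up (adjusted p = 0.513). The called members of the bile acid (Cyp7b1, Slco1a1) and xenobiotic lists (Cyp2a4, Cyp2b9, Cyp2b13, Cyp3a41a) differ between the sexes in mouse liver, and the same 3 livers held Xist and fewer Y-linked reads, so these list results were not separable from that pattern. Of 24 cholesterol synthesis genes 0 passed (median 0.0674; camera adjusted p = 0.421), and 5 rose in read counts, among them Sqle, the squalene epoxidase, at 20.1 ± 2.33 against 12.1 ± 1.19 (0.74, adjusted p = 3.06e-05).

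For cell type lists, 0 of 17 Kupffer cell genes passed and 5 fell adjusted over the list alone (median -0.465; camera adjusted p = 8.06e-08; adjusted p = 0.453 with an estimated correlation). In read counts Cd163 fell to 0.4659 ± 0.112 (-1.60, adjusted p = 0.00142) and Marco, a scavenger receptor, fell by 1.23 (adjusted p = 0.0236). Monocyte genes (9 tested, median 0.435, camera adjusted p = 0.00162) and hepatocyte genes (15 tested, median -0.33, camera adjusted p = 0.00295) lost their calls, with adjusted p = 0.453 and adjusted p = 0.88 with an estimated correlation. The same held for p53 (13 genes, median 0.326, camera adjusted p = 0.00999), NRF2 (median 0.192, adjusted p = 0.0111), lipoprotein (29 genes, median -0.122, adjusted p = 0.0267) and periportal genes (12, median -0.257, adjusted p = 0.031), at adjusted p = 0.847 for p53 and 0.88 for the others with an estimated correlation. Of 17 purine genes 0 passed and 1 fell adjusted over the list alone, with a median of 0.0523 although the camera direction was down (adjusted p = 0.721). Of 16 genes of small RNA silencing and nucleic acid sensing 0 passed (median 0.061; camera adjusted p = 0.564). Camera called 16 of 34 lists, 9 up and 7 down.

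Limma called 51 genes at 2 mg/kg, 30 higher and 21 lower (663 at unadjusted p below 0.05), and edgeR on recovered reads called 764, 388 higher and 376 lower, with 50 in common. Hprt was log2 -0.99 ± 0.33 by limma (adjusted p = 0.138) and -0.98 ± 0.12 by edgeR (adjusted p = 2.36e-05). The limma count fell to 13 without liver 3 and to 13 without liver 36 of the 2 mg/kg group, and the edgeR count to 361 and 379. Planted changes of 1.5, 2 and 4-fold were recovered at 0%, 4.88% and 71.4% by limma (10594 genes run) and at 22.4%, 59.3% and 88.9% by edgeR (10526 genes). Unchanged genes made up 2% of the limma calls and 4.03% of the edgeR calls in these planted data.

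The comparison of 2 mg/kg (n = 3) with 0.2 mg/kg (n = 8) asked which transcripts differed between the doses. As against controls, the dose was not separable here from the Xist and Y-linked pattern of the 3 livers at 2 mg/kg. Saa3 rose from 461 ± 248 to 3513 ± 926 (log2 fold change 3.20 ± 0.60, adjusted p = 0.02), Lcn2 from 92.6 ± 48.3 to 954 ± 259 (3.64 ± 0.59, adjusted p = 0.00347) and Apcs from 154 ± 36.3 to 705 ± 120 (2.23 ± 0.41, adjusted p = 0.0195). Nat8f5, an N-acetyltransferase, fell from 26.2 ± 3.597 to 7.80 ± 4.03 (-1.87 ± 0.31, adjusted p = 0.0023), and Hspa1b, an inducible HSP70, from 26.9 ± 9.04 to 8.04 ± 2.29 (-1.70 ± 0.40, adjusted p = 0.0447). The Hspa1b call was lost in 9 of 11 fits that left out 1 liver. Sult2a1 rose by 5.68 ± 0.79 (adjusted p = 0.000993), Cyp2a4 by 2.93 ± 0.30 (adjusted p = 1.61e-05) and Xist by 4.15 ± 0.67 (adjusted p = 0.00347), and Mup7 fell by 1.63 ± 0.30 (adjusted p = 0.00581). Hprt was at -0.87 ± 0.32 by limma (adjusted p = 0.577) and -0.86 ± 0.12 by edgeR (adjusted p = 0.00013).

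Between the doses, 6 of 31 acute phase genes rose and 0 fell (19 rose in read counts), and 17 rose adjusted over the list alone (median 0.957; camera adjusted p = 4.49e-54; adjusted p = 0.0108 with an estimated correlation). Of 4 neutrophil genes 1 rose, and 4 rose adjusted over the list alone (median 1.80; camera adjusted p = 3.6e-14; adjusted p = 0.00663 with an estimated correlation). The called gene was again Lcn2, a member of the acute phase list too. In read counts with an estimated correlation neither the acute phase (adjusted p = 0.0782) nor the neutrophil list (adjusted p = 0.139) was called, nor any other. S100a8, a neutrophil calcium-binding protein, reached 39.2 ± 18.03 against 11.2 ± 4.69 and rose in the read counts (1.80, adjusted p = 0.0436), a call lost in 9 of 11 fits without 1 liver. Of 20 cytokine genes 1 rose, Il1rn (1.97 ± 0.37, adjusted p = 0.0237), and 1 rose adjusted over the list alone. The list had a median of 0.49 (camera adjusted p = 2.23e-10; adjusted p = 0.261 with an estimated correlation). None of 32 type I interferon genes passed between the doses (median 0.334; camera adjusted p = 1.37e-05; adjusted p = 0.941 with an estimated correlation). In read counts 5 rose, with Ifit1 at 49.5 ± 28.6 against 18.2 ± 2.31 (1.44, adjusted p = 0.00167). The interferon gamma list was lower at 2 mg/kg (0 of 26 passed; median -0.262; camera adjusted p = 0.000627; adjusted p = 0.941 with an estimated correlation). In read counts 4 members fell. Iigp1, an immunity-related GTPase, was at 163 ± 28.6 against 276 ± 33.6 (-0.76, adjusted p = 0.00105).

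Fatty acid synthesis (median -0.487; camera adjusted p = 1.22e-08; adjusted p = 0.796 with an estimated correlation) and bile acid genes (median -0.303; camera adjusted p = 9.79e-07; adjusted p = 0.918 with an estimated correlation) were lower without a gene called by limma. Read counts fell for 5 and 6 of their members, such as Me1, the malic enzyme (-0.86), and Cyp8b1 (-0.88). As against controls, the bile acid result was not separable from the Xist and Y-linked pattern of the 3 livers at 2 mg/kg. Camera calls for the unfolded protein (median 0.362, adjusted p = 0.00106), clock (-0.288, adjusted p = 0.00231), stellate cell (0.227, adjusted p = 0.00428) and Kupffer cell lists (-0.287, adjusted p = 0.01) were each lost at adjusted p = 0.941 with an estimated correlation. The T and NK cell list (median 0.528, camera adjusted p = 0.0292) was lost at adjusted p = 0.422 with an estimated correlation. In read counts 7 NRF2 genes fell, with Ugdh at 36.6 ± 5.54 against 60.4 ± 5.05 (-0.73, adjusted p = 0.000274), and Pecam1 fell from 29.6 ± 11.1 to 6.90 ± 1.315 (-2.10, adjusted p = 0.00337). Gbp10, a guanylate-binding protein, was at 0.566 ± 0.322 against 4.25 ± 2.23 and fell in read counts (-2.86, adjusted p = 0.00341). Camera called 12 of 34 lists, 7 up and 5 down.

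Limma called 30 genes between the doses, 19 higher and 11 lower (63.3% higher; 391 at unadjusted p below 0.05). EdgeR called 593, 309 higher and 284 lower (52.1% higher), and 29 genes were shared. Without liver 3 or liver 36 of the 2 mg/kg group limma called 7 or 10 and edgeR 229 or 324. Recovery of planted 1.5, 2 and 4-fold changes was 0%, 0% and 71.9% for limma (10568 genes run) and 30.8%, 60.8% and 85.9% for edgeR (10476 genes). Unchanged genes made up 2.13% of the limma calls and 3.91% of the edgeR calls in these planted data.

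BLT-1 before 0.2 mg/kg (n = 4) was compared with 0.2 mg/kg alone (n = 8) to see which transcripts differed when the receptor blocker preceded the particles. Limma on the deposited scale called 0 genes (206 at unadjusted p below 0.05), and the edgeR read-count test called 10 genes, 3 higher and 7 lower (777 at unadjusted p below 0.05). DESeq2 called 96 and limma voom 25. The named genes with the smallest limma p were Pecam1 (log2 fold change -2.18 ± 0.45, adjusted p = 0.901), Orm3, an acute phase lipocalin (1.26 ± 0.35, adjusted p = 0.994), and Ccl7 (-1.71 ± 0.39, adjusted p = 0.994), none of which passed. By edgeR, Iigp1 fell from 276 ± 33.6 to 155 ± 25.5 (-0.84 ± 0.12, adjusted p = 0.00626), and Rtp4, an interferon-induced receptor transporter, from 22.3 ± 2.33 to 12.9 ± 1.10 (-0.80 ± 0.12, adjusted p = 0.00728). Pecam1 fell from 29.6 ± 11.1 to 6.001 ± 1.44 (-2.30 ± 0.37, adjusted p = 0.0151), with controls at 11.6 ± 5.44. Tsc22d3, a glucocorticoid-induced leucine zipper protein, rose from 21.6 ± 2.06 to 37.8 ± 4.83 (0.81 ± 0.15, adjusted p = 0.0286). Fmo5, a flavin monooxygenase, rose from 75.7 ± 8.23 to 102.5 ± 5.995 (0.44 ± 0.08, adjusted p = 0.0286), and Gstt3, a glutathione transferase, from 19.5 ± 1.84 to 25.4 ± 1.84 (0.38 ± 0.07, adjusted p = 0.0322). With animal number ranges as a block edgeR called 4 genes, 0 higher and 4 lower, so these 3 calls were lost. None of the BLT-1 livers and 4 of the 8 livers at 0.2 mg/kg had animal numbers from 27 to 39. Without liver 6 or liver 7 of the BLT-1 group edgeR called 0 genes. The count was 18 without liver 19, and 3 or 6 without liver 4 or liver 17 of the 0.2 mg/kg group.

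Genes of the interferon lists had lower values with BLT-1, but 0 of 32 and 0 of 26 passed by limma. The median was -0.562 for type I interferon (camera adjusted p = 7e-22; adjusted p = 0.358 with an estimated correlation) and -0.483 for interferon gamma (camera adjusted p = 1.1e-15; adjusted p = 0.358 with an estimated correlation). In read counts 1 gene fell in each list. Isg15 was at 80.4 ± 26.95 against 138 ± 43.2 (-0.77 ± 0.44, adjusted p = 0.994) and Irf7 at 22.8 ± 1.86 against 27.7 ± 4.20. None of 31 acute phase genes passed, and 2 rose adjusted over the list alone (median 0.347; camera adjusted p = 6.29e-17; adjusted p = 0.358 with an estimated correlation). Orm2 was at 598 ± 218 against 256 ± 133 and Saa1, a serum amyloid, at 13370 ± 3239 against 5863 ± 2806, without a call. Cholesterol synthesis (median -0.206, camera adjusted p = 0.000655), gluconeogenesis (0.154, adjusted p = 0.00461) and pericentral genes (0.111, adjusted p = 0.0294) were each at adjusted p = 0.986 with an estimated correlation. For T and NK cell genes the median was -0.18 (camera adjusted p = 0.0287; adjusted p = 0.358 with an estimated correlation). Camera called 7 of 34 lists, 3 up and 4 down, and 0 with an estimated correlation. Planted 1.5, 2 and 4-fold changes were recovered at 0%, 9.88% and 78.1% by limma (10594 genes run) and 31.8%, 66.2% and 92.1% by edgeR (10485 genes). Unchanged genes made up 1.69% of the limma calls and 7.69% of the edgeR calls in these planted data. No group received BLT-1 without particles, so effects of BLT-1 itself were not separable.

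For BLT-1 plus 0.2 mg/kg (n = 4) against controls (n = 7) the question was which transcripts differed after both treatments. Cxcl9 was the only gene called by limma, rising from 8.23 ± 2.31 to 51.0 ± 29.3 (log2 fold change 2.50 ± 0.43, adjusted p = 0.0367). Other genes of the interferon lists did not pass by limma. Gbp3 was at 7.45 ± 1.90 against 2.08 ± 0.540 (adjusted p = 0.0938), Irf7 at 22.8 ± 1.86 against 8.13 ± 2.27 (adjusted p = 0.0938), Zbp1 at 34.7 ± 9.74 against 11.2 ± 3.20 (adjusted p = 0.0938) and Psmb8 at 35.2 ± 4.87 against 13.8 ± 2.42 (adjusted p = 0.172). These 4 rose in the read-count test, by 1.83, 1.48, 1.63 and 1.35. Of the interferon gamma list 1 gene of 26 rose (10 of 25 in read counts), and 4 rose adjusted over the list alone (median 0.50; camera adjusted p = 1.37e-15; adjusted p = 0.354 with an estimated correlation). Of 32 type I interferon genes 0 passed (13 rose in read counts), and 11 rose adjusted over the list alone (median 0.622; camera adjusted p = 1.94e-25; adjusted p = 0.354 with an estimated correlation).

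NRF2 genes had a median of 0.306 with 0 of 21 passing and 4 risen when adjusted over the list alone (camera adjusted p = 1.66e-09; adjusted p = 0.514 with an estimated correlation). In read counts 7 rose and the list held (adjusted p = 0.00493 with an estimated correlation). Ugdh was at 61.7 ± 4.82 against 31.6 ± 3.58 (0.96, adjusted p = 3.22e-06) and Gstm3 at 84.2 ± 14.97 against 40.3 ± 5.46. Unfolded protein genes had a median of -0.369 (camera adjusted p = 4.01e-10; adjusted p = 0.525 with an estimated correlation). In read counts 5 fell, with Sdf2l1 at 10.6 ± 2.07 against 21.5 ± 6.56 (-1.02, adjusted p = 0.00287). Fatty acid oxidation had a median of -0.261 (camera adjusted p = 5.13e-09; adjusted p = 0.663 with an estimated correlation) and 6 genes fell in read counts, among them Acot1 (-1.12, adjusted p = 0.0111). Acute phase genes had a median of 0.321 with 3 risen adjusted over the list alone (camera adjusted p = 1.75e-08; adjusted p = 0.663 with an estimated correlation). In the clock list (median 0.17, camera adjusted p = 0.016; adjusted p = 0.987 with an estimated correlation) 3 genes rose and 1 fell in read counts, with Nr1d1, a repressor of the clock, down by 1.08 (adjusted p = 0.0471). Cholesterol synthesis genes had a median of -0.207 (camera adjusted p = 0.00102; adjusted p = 0.987 with an estimated correlation). Among 3 that fell in read counts was Hmgcs1, the HMG-CoA synthase (-0.51, adjusted p = 0.0284). Kupffer cell genes (median -0.25, camera adjusted p = 3.28e-05), monocyte genes (0.386, adjusted p = 9.86e-06) and B and plasma cell genes (-0.443, adjusted p = 0.0036) were at 0.722, 0.354 and 0.354, each an adjusted p with an estimated correlation.

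Limma called 1 gene for BLT-1 plus particles against controls (315 at unadjusted p below 0.05), edgeR on recovered reads 292, 178 higher and 114 lower, and camera 11 of 34 lists, 6 up and 5 down (0 with an estimated correlation). The Cxcl9 call held without liver 6 of the BLT-1 group and was lost (0 genes) without any other single liver. The edgeR count fell to 153, 170 or 176 without BLT-1 liver 19, 7 or 6. Planted 1.5, 2 and 4-fold changes were recovered at 0%, 3.66% and 70.3% by limma (10579 genes run) and 38.5%, 71.2% and 81.2% by edgeR (10511 genes). Unchanged genes made up 0% of the limma calls and 6.29% of the edgeR calls in these planted data.

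Genes called against the same controls were compared between treatments. At 0.2 and 2 mg/kg 8 genes were higher in both by limma (0.0618 by chance). Simulated data with shared controls and no change called 0 or 1 genes per comparison and direction, so their overlap of 0 sets no bar for these counts. With split controls limma called 0 genes higher at 0.2 mg/kg in 1 split, where no overlap was possible. In the other 9 and 18 genes were higher, with 0 in common. In read counts 138 genes were higher in both (10.7 by chance, 76 and 86 with split controls), 75 were lower in both (8.49 by chance, 23 and 28 with split controls) and 11 went opposite ways. The covariance of the fold changes was 0.395, against 0.152 in simulated data, and their correlation 0.511 (simulated 0.310 to 0.457). With split controls, where no control was shared, the covariance was 0.157 and 0.147 and the correlation only 0.147 and 0.141. With and without BLT-1 at 0.2 mg/kg, 122 genes were higher in both (4.93 by chance, 65 and 53 with split controls) and 73 lower in both (2.57 by chance, 16 and 11 with split controls), with covariance 0.320 against 0.155 simulated. Their correlation of 0.481 lay inside the simulated range of 0.362 to 0.513. It was 0.0877 and 0.146 with split controls, with covariance 0.0876 and 0.137. For BLT-1 plus 0.2 mg/kg and 2 mg/kg the counts were 77 and 48 (6.42 and 3.98 by chance; 36 and 51 higher and 11 and 21 lower with split controls), with covariance 0.363 against 0.182 simulated. Their correlation of 0.393 also lay inside the simulated range, 0.267 to 0.419. It was 0.0981 and 0.0444 with split controls, with covariance 0.111 and 0.0522.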

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

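All tests of explanations and of regrouped libraries in this part were chosen after the results were seen, while the sex chromosome list was fixed before. Single values were listed if a gap test set 1 library apart from the others of its group, a test by which chance flags about 1 in 20 groups. It was run only on groups of at least 4 livers, so the 3 livers at 2 mg/kg were not tested. It set apart 15 of 168 groups, all printed here in CPM with the nearest other library of the group in brackets. Control 1 was low in Irf7 at 3.17 (8.46), Ifi44 at 2.34 (7.01), Cyp3a41a at 0.414 (1.92) and Saa3 at 31.6 (385). Control 27 was high in Serpina1e at 2935 (2084). At 0.2 mg/kg liver 5 was high in Cxcl9 at 121.8 (53.95) and Gbp10 at 9.55 (4.70) and low in Mup7 at 4185 (7654) and Cyp7b1 at 36.5 (57.2). Liver 4 was low in Apcs at 70.4 (137) and high in Slco1a1 at 41.3 (33.6), and liver 31 was high in Sqle at 18.6 (15.6). With BLT-1, liver 20 was low in Ugdh at 54.6 (63.1) and high in Il1rn at 2.95 (1.60), and liver 19 was low in Orm2 at 275 (667).

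Regrouping asked how many splits of the same libraries called as many genes as the real groups, the real one included. By limma this was 1 of 100 for 0.2 mg/kg against controls, 2 of 100 for 2 mg/kg against controls and 1 of 100 between the doses, so chance regrouping alone is an unlikely source of these counts. It was 100 of 100 for BLT-1 against 0.2 mg/kg, where the real count was 0. For BLT-1 against controls it was 20 of 100, so a count of 1 call could be chance. Because calls of any gene were counted, Cxcl9 itself was not tested by regrouping. Splits reached 313 and 5811 called genes in the comparisons of 2 mg/kg and of BLT-1 with controls. The 5811 came from controls 2, 14 and 28 with BLT-1 liver 6, whose deposited factors were 1.21 to 1.30 times those from genes. The remaining libraries of that comparison were at 0.56 to 1.17. The 313 came from controls 1, 15 and 27 at 0.632 to 0.780, a range that also held liver 3 at 2 mg/kg (0.763). A part played by the spike-in scale in these splits was not tested. In read counts the real groups alone reached their count in each comparison (1 of 40), and the highest other splits called 1, 102, 24, 3 and 36 genes.

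At 2 mg/kg each of the 3 livers held Xist at 2.812 CPM or more, while the other 19 libraries held at most 0.313, and summed Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty were at 49.81% of the other libraries (Ddx3y 43.0%, Eif2s3y 50.5%, and without a call Kdm5d 64.7%, adjusted p = 0.686, and Uty 79.5%, adjusted p = 0.87). RNA of female animals in these libraries could give that pattern. A shift of sex-biased liver genes in male animals would not raise Xist, so the value of 2.812 speaks against it, and reads moved from Ddx3y to Ddx3x would give an equal gain, whereas Ddx3x gained 1.778 against a loss of 9.975 (standard error 1.08). Y-linked reads stayed at 48.18 to 51.29% of the other libraries in each of the 3, so none held female RNA alone. At 0.2 mg/kg Xist was at 0.1535 ± 0.104 against 0.161 ± 0.0959 in controls, so the lower dose gave no such rise. Within 2 mg/kg the particle dose and female RNA cannot be told apart, because 0 libraries at that dose lacked the pattern. Male and female livers side by side, 1 animal per library, would differ in Xist and Y-linked reads between libraries. The 3 libraries were alike, with Y-linked reads at 49.96, 51.29 and 48.18%, which argues against such a group. Whether RNA of several animals was mixed within each library was not tested.

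Lower Hprt at 2 mg/kg was not removed by any scaling, with the fold change nearest to 0 at log2 -0.8397 over 21 settings (lowest -1.241). These were not 21 scalings. Filters, pseudocounts, the limit, the block and the libraries fitted also varied among them, and some fits were counted more than once. Of 1517 genes of like level 35 were as low (2.31%) in read counts, so few of them fell as much as Hprt. TMM scaling held the median of all genes at log2 -0.00789, so a fall shared by most genes could not show in this count. On the deposited scale that median was log2 -0.226, against -1.213 for Hprt. Hprt is X-linked, and 0 libraries at 2 mg/kg had Xist at the level of the others. A part played by female RNA therefore cannot be excluded. Summed Y-linked reads were at 49.81% of the other libraries by a ratio of means. By mean log2 values Hprt was at 50.8% of controls and 54.7% of 0.2 mg/kg, so the bases are unlike. If Y-linked reads measure the male share, female RNA could give the whole fall only if it held little or no Hprt. These values argue against female RNA as the source of the whole difference.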

How the results depend on the processing

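Chosen after the results were seen were the read-count test with TMM and all tests of its settings, camera on read counts, read-count overlaps, the TMM rescaling and the fit without controls 28 and 29. The remaining alternatives to limma on the deposited scale were chosen before. No paired analysis was possible because each animal number is unique and none is shared by groups. Counts follow the order 0.2 mg/kg, 2 mg/kg, 2 against 0.2 mg/kg, BLT-1 against 0.2 mg/kg and BLT-1 against controls, where limma on the deposited scale gave 23, 51, 30, 0 and 1. On recovered reads edgeR with TMM gave 541, 764, 593, 10 and 292, with RLE 554, 763, 583, 10 and 296, DESeq2 699, 898, 721, 96 and 469, voom 606, 1114, 919, 25 and 378, and limma after TMM rescaling 616, 870, 639, 10 and 324. With spike-in factors edgeR gave 25, 63, 29, 0 and 0, so the larger counts went with scaling on genes, and the cause was not tested. Only the groups compared gave 41, 38, 42, 0 and 3, and leaving out controls 28 and 29 gave 14, 64, 34, 0 and 0. A limit of 0.01 gave 16, 15, 11, 0 and 0. For BLT-1 against controls pseudocount 10, no filter and the block each gave 0. The read-count test gave 265, 404, 273, 2 and 125 at a limit of 0.01, 511, 311, 536, 8 and 182 with only the groups compared, and 4 for BLT-1 against 0.2 mg/kg with the block, 0 higher and 4 lower.

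Hprt at 2 mg/kg against controls became called in read counts at log2 -0.9826 (RLE, adjusted p = 2.37e-05), -0.9888 (DESeq2, 7.07e-13), -1.012 (voom, 5.34e-06), -0.9819 (edgeR TMM, 2.36e-05) and -0.9739 (limma after TMM, 1.46e-05). In the same order it was -0.8555 (adjusted p = 0.000138), -0.8596 (5.75e-10), -0.955 (7.43e-06), -0.8599 (0.00013) and -0.8662 (5.62e-05) between the doses. These and the following values are not shifted to the median of all genes. For BLT-1 against 0.2 mg/kg Hprt was at -0.03153 (adjusted p = 0.996), -0.03063 (1), -0.03121 (0.945), -0.03662 (0.999) and -0.03739 (0.969). The limma value there was positive only before the shift to the median of all genes and -0.03 after it, so the sign turned with the shift alone. Scarb1 was called at 0.2 mg/kg by voom alone (-0.2266, adjusted p = 0.0371), and at 2 mg/kg against controls it was at 0.02343 (RLE), 0.03239 (DESeq2), 0.02521 (edgeR TMM) and 0.02737 (limma after TMM). Its limma value was -0.21 before the shift and 0.01 after it. The cause of the other changes was not tested.

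Leaving out single livers moved the limma counts over 18 to 32, 13 to 63, 7 to 34, 0 to 1 and 0 to 1, and the edgeR counts over 434 to 545, 361 to 947, 229 to 747, 0 to 18 and 153 to 279. Before the shift to the median, Hprt ran by limma from -0.1026 (without liver 7) to 0.2852 (without liver 6) for BLT-1 against 0.2 mg/kg and from -0.329 to 0.05885 against controls. Scarb1 ran from -0.1126 to 0.244 between the doses (without livers 3 and 16 of 2 mg/kg) and from -0.2901 to 0.1237 for BLT-1 against controls (without livers 7 and 6).

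Lists called were 2, 4, 2, 0 and 0 with an estimated correlation, 2, 0, 1, 0 and 0 by fry, and 3, 2, 0, 0 and 1 in read counts with an estimated correlation. With split controls 0 and 0 genes were shared as higher by limma between 0.2 mg/kg and 2 mg/kg, and 0 and 0 between 0.2 mg/kg with and without BLT-1. In both splits limma called 0 genes higher with BLT-1, so no overlap was possible for that pair. In read counts the shared genes were 76 and 86 higher and 23 and 28 lower for the first pair, and 65 and 53 higher and 16 and 11 lower for the second. For BLT-1 with 2 mg/kg they were 36 and 51 higher and 11 and 21 lower. Of 2369 values of 115 named gene results 2092 stayed, 277 were weaker and 0 reversed. Depth of 7152596 to 15101565 reads limits genes of low level, such as Xist with at most 3 reads in 19 libraries.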

Other observations

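The gene groups of this part were chosen after the results were seen, over 25 tests, and use the read counts. MHC class I and peptide loading genes (15 tested) were higher in 11 members at 0.2 mg/kg (median log2 0.62; camera adjusted p = 0.000131 with an estimated correlation), in 10 at 2 mg/kg with 1 lower (0.554; adjusted p = 0.00184) and in 10 with BLT-1 against controls (0.616; adjusted p = 0.000335). With BLT-1 against 0.2 mg/kg 0 differed (adjusted p = 0.406), and between the doses 2 were higher and 2 lower (adjusted p = 0.62). Of 21 Mup genes 17 were lower at 2 mg/kg against controls, 12 of them also by limma (median -1.38; adjusted p = 0.00704), and 14 were lower against 0.2 mg/kg (median -1.11; adjusted p = 0.00925). The Mup group was not called at 0.2 mg/kg against controls (adjusted p = 0.359), with BLT-1 against controls (adjusted p = 0.406) or with BLT-1 against 0.2 mg/kg (adjusted p = 0.982). Mup genes have higher levels in male liver, so the Mup result at 2 mg/kg was not separable from the Xist and Y-linked pattern of the same 3 livers.

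Of 83 cytosolic ribosomal protein genes 47 were lower at 0.2 mg/kg (median -0.174; adjusted p = 0.0457 with an estimated correlation) and 63 were higher at 2 mg/kg against 0.2 mg/kg (0.307; adjusted p = 0.00925). The group was not called at 2 mg/kg against controls (9 higher; adjusted p = 0.254), with BLT-1 against controls (13 lower; adjusted p = 0.109) or with BLT-1 against 0.2 mg/kg (adjusted p = 0.714). Of 19 translocon genes of the endoplasmic reticulum 8 were lower at 0.2 mg/kg (-0.185; adjusted p = 0.00925), 13 were higher at 2 mg/kg against 0.2 mg/kg (0.399; adjusted p = 0.00157) and 4 were lower with BLT-1 against controls (-0.173; adjusted p = 0.0347). They were not called at 2 mg/kg against controls (5 higher; adjusted p = 0.109) or with BLT-1 against 0.2 mg/kg (adjusted p = 0.615). Among 13 mitochondrially encoded genes 10 were lower at 0.2 mg/kg (-0.339; adjusted p = 0.00704). The other comparisons did not call them, at adjusted p = 0.169 for 2 mg/kg and 0.0885 for BLT-1 against controls, 0.339 between the doses and 0.126 for BLT-1 against 0.2 mg/kg. Limma on the deposited scale called 0 genes of these groups.

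Cyp3a41a held 469, 1285 and 1722 reads in the 3 livers at 2 mg/kg. In the other groups it held 3, 0, 2, 0 and 1 reads in control 1, livers 4 and 5 at 0.2 mg/kg and livers 6 and 7 with BLT-1, and 15 to 34 reads in the remaining 14 libraries. Livers with 3 reads or fewer all had animal numbers from 1 to 13, although control 2 of that range was not among them. Sult3a1 held 275, 416 and 657 reads and Xist 39, 39 and 57 reads at 2 mg/kg. The other 19 libraries together held 28 reads of Xist, 77 of Sult2a1, 207 of Sult3a1, 351 of Cyp3a41a and 18 of Cyp2b13. Of genes with higher levels in male liver, picked after their values were seen, Cyp2d9 was at 56.9%, Cyp4a12a at 53.9%, Mup20 at 54.7% and C6 at 52.3% of the other libraries at 2 mg/kg. Others were lower still, such as Mup7 at 2746 ± 1061 against 9803 ± 1889 CPM and Cyp7b1 at 27.1 ± 8.63 against 68.7 ± 13.5 in controls.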
